A study of Zea mays with 6 samples.

How the data were processed

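Root tips of maize seedlings grown with or without nitrate were profiled by droplet single-cell RNA sequencing, 1 library per condition, and by bulk RNA sequencing, 2 libraries per condition. Per the labels' protocols, roots were digested to protoplasts and libraries were made with a single-cell 3' kit; the labels give this same text for the bulk samples, so how the bulk libraries were made remains unclear. The single-cell values are whole-number UMI counts per gene and barcode, deposited as sparse matrices whose headers name Cell Ranger's matrix format with version 3.1.0, and the submitters' processing notes name Cell Ranger and the genome build B73 RefGen_v4. How the deposited barcodes had been selected is not given in the sources used here; the lowest barcode held 500 UMIs in each library. The bulk values are raw counts per gene, deposited without normalisation; the aligner, the counting tool and its strand setting are not given in the sources used here. Counts of overlapping, antisense or near-identical genes are therefore uncertain. No file gave cell annotations.

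Each sample's group came from its labels. The bulk tables listed 45953 genes and the single-cell matrices listed 46430. Names were taken from a RefSeq table of a later assembly of B73, by exact match of identifiers: 0 of 44146 nuclear gene models and 365 of 365 organelle genes matched. The 37 gene lists and cell type marker lists fixed before the data were examined, which cover nitrate uptake and reduction, nitrogen assimilation, hormones, stress, nutrient uptake and root cell types, found 0 members by name. The lists gave no result, and the planned camera test on them and the planned clustering without cell cycle genes were not run. Identifiers recalled beforehand for some lists could not be checked against a name and were not used as members. Zm00001d018161 was among them, for nitrate and nitrite reduction. The rule for named genes asked, in bulk, for the largest changes past the threshold with a name, which gave none, and in single cells for named genes with at least 100 UMIs and a ratio of at least 2 either way, which gave 1. Other organelle genes and the 4 identifiers in the text were chosen after their values were seen; the identifiers are the 2 per direction with the smallest p in the fit over all 6 libraries.

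Bulk counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM normalisation, the filterByExpr filter and Benjamini-Hochberg adjustment, at an adjusted p under 0.05; all fold changes are without over with nitrate. Standard errors were taken as the log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 0.194. Tested on simulated data with 200 changed genes among 24049, the edgeR test recovered 42% of genes changed 2-fold, 92% at 4-fold, 92% at 8-fold and 100% at 16-fold, and 12.4% of its 186 calls were false. DESeq2 had 20.3% false among 207 calls. Both false shares were above the 0.05 aimed for. The counts were drawn from the fitted dispersions with no other variation between libraries. The recovered shares may therefore not hold for the real libraries, where a gene at a log2 fold change of -3.82 was not called. Alternatives were RLE size factors, library size alone, DESeq2 1.42.0, limma-voom (limma 3.58.1), other filters, a fold threshold, a block on the replicate number and leaving out each library. Leaving out a library left 1 in its group, so the spread in such a fit came from the other group alone. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 31.5 with nitrate and 18.5 without, so neither pair was 1 library deposited more than once; any separately prepared libraries would exceed this noise, so it does not show separate plants. Gene sets were the 100 genes with the highest fold of each cluster over the other cells in both libraries, among genes tested in bulk, plus the genes of the mitochondrial genome, and were tested with camera on voom values and with fry.

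Single cells were processed with scanpy 1.11.5. Barcodes with at least 500 detected genes were kept, which removed 723 of 3790 with nitrate and 617 of 3426 without. Scrublet at an expected rate of 3% called 0 of 3067 and 0 of 2809 cells, so it has not worked here and doublets remain; an alternative left out the 102 and 92 cells with the highest scores. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were scaled within each library and clipped at 10, and 30 principal components with 15 neighbours were clustered by the Leiden method at a resolution of 0.8. Alternatives were resolutions of 0.5 and 1.2, scaling over both libraries, a minimum of 1000 genes and every deposited barcode. No test was made between these libraries. UMIs were summed per library or cluster and given as CPM, with exact Poisson intervals for sums, exact conditional binomial intervals for ratios and Clopper-Pearson intervals for shares, at 95%; these cover counting error only. For background RNA, a bound on UMIs of a gene per cell was taken from the cluster with the lowest upper Poisson limit, adjusted for the 19 clusters, and was taken off the library with the higher level. On simulated counts with a true ratio of 1.5 the ratio interval covered it in 96.5% of 4000 genes at a mean of 20 UMIs. A count of 0 was given a floor of 3 UMIs per library and cluster. For the thinned alternative each cell was reduced to 1000 UMIs, which left out 549 cells with nitrate and 445 without.

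Bulk and single-cell changes were compared over genes with at least 20 UMIs. The planned comparison over genes called in bulk had no genes, so all genes expressed in both took its place. Equal weighting of clusters averaged CPM over the 19 clusters in each library, with a pseudocount of 0.5. To part shares of cells from UMIs per cell, the profiles of the clusters were also mixed with either of these set to the mean of both libraries and the other kept as in each library.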

Results

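The series measured messenger RNA in the terminal 2 cm of the primary root of the maize inbred line B73, the line from which the reference genome of the species was made. Seedlings had grown for 4 days on paper soaked in nutrient solution. One group received 4 mM calcium nitrate, and the other received 4 mM calcium chloride in its place, so that calcium was matched while nitrate was absent and chloride was raised. Each condition had 1 droplet single-cell library and 2 bulk libraries numbered as replicates. The comparison asked which transcripts, and in which cells of the root tip, differed when nitrate was withheld. Nothing in the labels said that the 2 bulk replicates of a group came from separate plants, so p-values measured only the spread between these libraries, which may be technical.

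The bulk libraries with nitrate held 22495543 and 25673175 counts, and those without nitrate held 26512297 and 20103887. The single-cell library with nitrate held 3790 barcodes and 16782208 unique molecular identifiers (UMIs, tags that count each captured RNA molecule once). The library without nitrate held 3426 barcodes and 18766447 UMIs. After barcodes with fewer than 500 detected genes were left out, 3067 cells with a median of 2040 UMIs remained with nitrate and 2809 cells with a median of 2189 UMIs remained without it. Intervals given below for single-cell values covered counting error only, because each condition had 1 library. The files did not pair the 44146 nuclear gene identifiers with names, and none of them matched the names at hand. All 365 mitochondrial and plastid genes did match, so genes with names below belong to the organelle genomes.

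In bulk root tips, Zm00001d018161 and Zm00001d017095 had lower counts without nitrate, and Zm00001d052194 and Zm00001d033710 had higher counts. Zm00001d018161 had 57.3 ± 15.5 CPM (counts scaled to library size) with nitrate and 3.99 ± 2.47 without it (SD, n = 2 each), a log2 fold change of -3.82 (SE 0.44). Zm00001d017095 had 44.9 ± 0.123 against 14.3 ± 0.626 CPM (SD, n = 2 each), a log2 fold change of -1.65 (SE 0.14). Zm00001d052194 went the other way, with 15.8 ± 1.09 CPM with nitrate and 35.6 ± 5.68 without it (SD, n = 2 each), a log2 fold change of 1.17 (SE 0.17). Zm00001d033710 was scarce, at 1.14 ± 0.161 against 3.82 ± 1.24 CPM (SD, n = 2 each), a log2 fold change of 1.74 (SE 0.38). These 4 identifiers had the smallest p-values in each direction in a fit over all 6 libraries, and were chosen after their values had been seen; such a fit favours genes that differ the same way in both assays. Of the genes picked by size in the single-cell libraries alone, 4 of 5 that were higher without nitrate and 3 of 6 that were lower had the same direction in bulk. These counts include Zm00001d033710 among the higher and Zm00001d018161 and Zm00001d017095 among the lower, so they are no separate check on the 4 identifiers. The gene with the lowest single-cell ratio in that pick, 0.0538, was higher in bulk, at a log2 fold change of 1.54 (SE 0.36). None of the 4 identifiers passed the test in the bulk libraries alone, where the adjusted p from edgeR's quasi-likelihood test was 0.166 for Zm00001d018161, 0.133 for Zm00001d017095, 0.166 for Zm00001d052194 and 0.179 for Zm00001d033710. DESeq2 gave the first 3 of these an adjusted p of 7.11e-18, 1.09e-11 and 1.71e-04, and none to Zm00001d033710. Over the 12 alternative fits, those with 1 library left out among them, the log2 fold change ran from -4.67 to -3.27 for Zm00001d018161. For Zm00001d017095 it ran from -1.69 to -1.61.

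**Figure D1:**
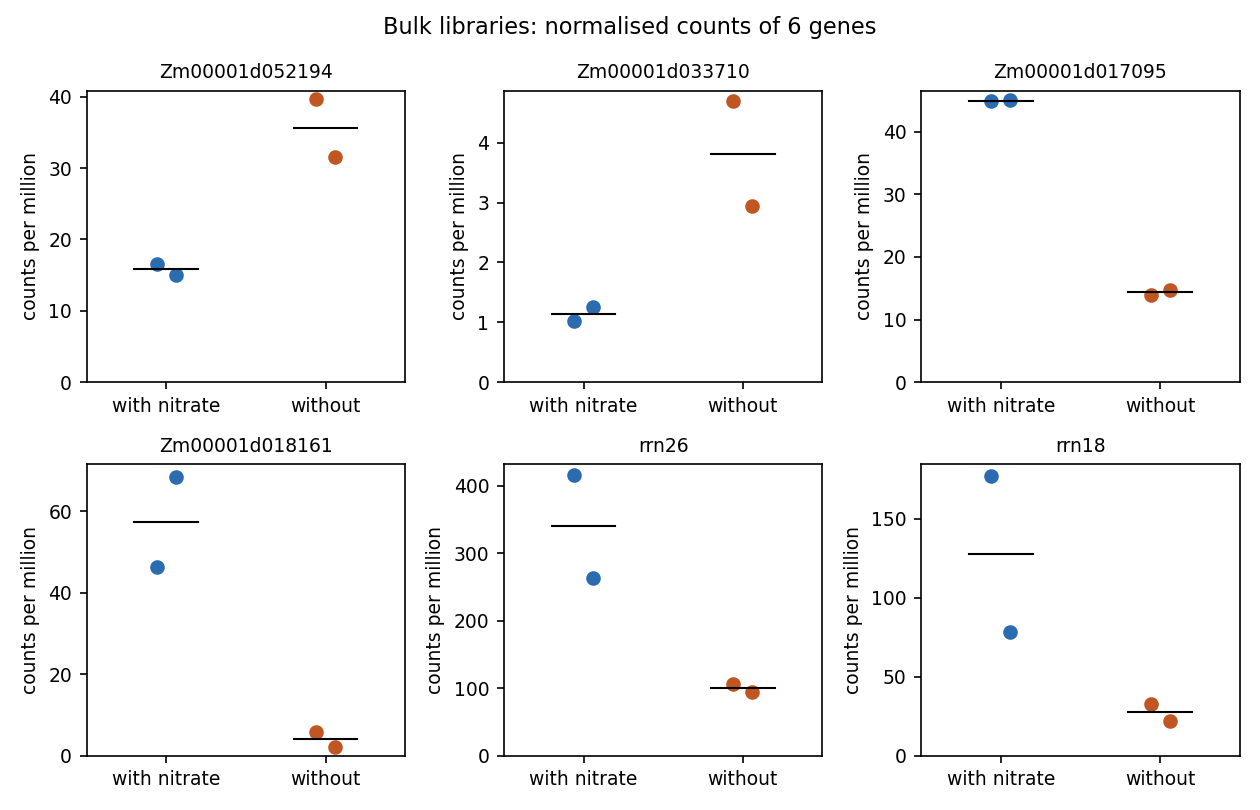
Normalised counts (CPM) in each bulk library for the 4 identifiers and for the mitochondrial ribosomal RNA genes rrn26 and rrn18. Points are libraries, 2 with nitrate and 2 without, and the horizontal line is the group mean; the groups did not overlap for any of the 6 genes, although none passed edgeR's adjusted threshold; DESeq2 called every one of them but Zm00001d033710.

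Over the 24049 genes tested, edgeR called 0 at an adjusted p under 0.05, and the lowest adjusted p was 0.133. At an unadjusted p under 0.05 there were 3960 genes, of which 1906 were higher and 2054 lower without nitrate. DESeq2 called 885 genes in the same libraries, 471 higher and 414 lower. Of these, 884 were among the genes edgeR tested, and every one of the 884 had the same direction and an unadjusted p under 0.05 there. The count also depended on single libraries: edgeR called 100 genes without the second library with nitrate and 38 without the first library lacking nitrate, but 0 without either of the others. It called 405 without a filter on low counts and, in a setting chosen after the data were seen, 1622 with a block that paired the first library of each group with the second of the other. Across genes, Pearson's r was 0.973 between the 2 libraries with nitrate and 0.978 between the 2 without, and 0.953, 0.963, 0.969 and 0.974 between libraries of different groups. By Spearman's rho, both pairs within a group (0.980 and 0.985) were above all 4 pairs between groups (0.961 to 0.979). The first principal component, with 53.5% of the variance, separated the groups.

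Transcripts of the mitochondrial genome took a smaller share of the counts without nitrate in both assays. The large mitochondrial ribosomal RNA gene rrn26 had a bulk log2 fold change of -1.76 (SE 0.25), and the small one, rrn18, had -2.22 (SE 0.41). Among genes for subunits of the respiratory chain, cox2 had a log2 fold change of -2.89 (SE 0.68), nad4 one of -2.79 (SE 0.75), cox3 one of -2.29 (SE 0.96) and cox1 one of -0.76 (SE 0.53), with at most 0.845, 1.60, 2.76 and 1.96 CPM in any library; the unadjusted p was 0.0550 for cox3 and 0.205 for cox1. By contrast, the open reading frame orf101-a had a log2 fold change of 0.62 (SE 0.43). Of 13 mitochondrial genes tested in bulk, 9 had a negative fold change, 5 had an unadjusted p under 0.05 and 0 passed edgeR's adjusted threshold. DESeq2 gave rrn26 an adjusted p of 9.16e-09 and rrn18 one of 1.39e-06. Over the 12 alternative fits the log2 fold change ran from -2.03 to -1.40 for rrn26 and from -2.66 to -1.51 for rrn18. Mitochondrial ribosomal RNA made up 593 and 352 CPM of the libraries with nitrate against 135 and 116 in those without. The other mitochondrial genes together made up 21.4 and 13.4 against 8.41 and 12.7 CPM.

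In the single-cell libraries, rrn26 had a ratio of 0.705 without nitrate over with nitrate (95% interval 0.695 to 0.714, from 44906 and 35614 UMIs). The ratio was 0.679 for rrn18 (0.659 to 0.7003), 0.786 for cox1 (0.741 to 0.835), 0.699 for cox2 (0.610 to 0.799) and 0.644 for nad4 (0.554 to 0.748). For atp9, a subunit of the ATP synthase, it was 0.786 (0.738 to 0.836). Among named genes with at least 100 UMIs, the mitochondrial ribosomal protein gene rps7 had the lowest ratio, 0.438 (0.327 to 0.583), from 150 and 74 UMIs, and was the 1 named gene that met the size rule fixed before the data were examined. Of 47 mitochondrial genes with at least 100 UMIs, 33 had an interval below 1 and 0 had one above 1. Of 22 plastid genes, 7 lay below 1 and 0 above, with clpP, a protease subunit, at 0.749 (0.692 to 0.810). These ratios were taken on total UMIs, on which the median log2 ratio of all genes with at least 100 UMIs was -0.11. Scaling by the trimmed mean of M values moved all log2 ratios up by 0.13, and rrn26 was then at -0.37. The counts of intervals on either side of 1 were not repeated on that scale, where fewer would lie below 1. With every cluster weighted equally, the log2 ratio was -0.15 for rrn26 and -0.24 for rrn18.

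The single-cell libraries differed from each other by more than counting error. Across 15042 genes with at least 100 UMIs, the log2 ratio without over with nitrate ran from -0.78 at the 5th percentile to 0.46 at the 95th. A random split of the same UMIs gave -0.25 and 0.26. Summed UMIs also follow the makeup of the clusters described below. Cluster 5 held 3472275 UMIs with nitrate and 5928730 without, and cluster 15 held 1857100 and 3143270. All kept cells together held 1.63e+07 and 1.84e+07. Ratios of whole libraries thus do not separate this makeup from changes within cells. Zm00001d017095 had 122.7 CPM with nitrate and 19.6 without, a ratio of 0.160 (0.142 to 0.179). Zm00001d018161 had 198 UMIs with nitrate and 24 without, a ratio of 0.108 (0.0674 to 0.165). Zm00001d052194 was higher without nitrate at a ratio of 1.89 (1.80 to 1.99), and Zm00001d033710 at 3.29 (2.64 to 4.14). With every cluster weighted equally, the log2 ratio of Zm00001d017095 moved from -2.65 to -1.38 and that of Zm00001d033710 from 1.71 to 0.84, whereas Zm00001d018161 was at -3.19 and -3.58. In cells thinned to 1000 UMIs, the log2 ratio of Zm00001d052194 was 0.50 instead of 0.92. With 1 library per condition these differences had no replicate check.

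Clustering placed the 5876 cells in 20 clusters, 19 of which held at least 20 cells of each library. The clusters stayed unnamed, because the markers fixed beforehand could not be matched to identifiers by name, and the clusters are referred to by number from the largest to the smallest. The share of cells common to both makeups, summed over clusters, was 84.4%. Shares were compared for 7 clusters. In these, none of the 10 leading genes differed by 2-fold or more between the libraries with an interval excluding 1. Larger differences in percent of cells lay among the clusters left out. Cluster 9 held 6.62% with nitrate and 2.78% without, and cluster 10 held 5.87% and 2.95%. Cluster 5 held 5.67% and 9.40%, and cluster 2 held 7.92% and 13.5%. For clusters 9, 10 and 5 the intervals were apart under each of the other clusterings too. In clusters 9, 10, 5 and 2, respectively 1, 8, 1 and 4 leading genes differed, so these shares are less certain. Cluster 17 held 3.46% of cells with nitrate (exact binomial 95% interval 2.84 to 4.16) and 1.64% without it (1.201 to 2.18). Its intervals were apart under each of the 6 other clusterings too. Cluster 3 held 11.3% (10.2 to 12.5) against 8.72% (7.70 to 9.83), but the intervals of its best match were apart in 1 of the 6 others, with a lowest Jaccard index of 0.510; without the highest doublet scores the shares were 7.82% and 6.96%. Cluster 6 went the other way, from 6.46% (5.61 to 7.38) to 8.47% (7.47 to 9.56), although its best match under another clustering had a Jaccard index of as little as 0.335 and its intervals were apart in 1 of the 6. Cluster 16 held 2.09% (1.61 to 2.66) against 3.17% (2.55 to 3.88), with overlapping intervals that were apart in 3 of the 6, and a lowest Jaccard index of 0.174. Clusters 11, 12 and 18 held 3.13%, 3.097% and 2.48% of cells with nitrate and 3.03%, 3.06% and 2.49% without. In cluster 12 the median cell held 4544 UMIs with nitrate and 2858 without. Digestion to protoplasts precedes droplet capture and can set how many cells of each kind are recovered.

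**Figure D2:**
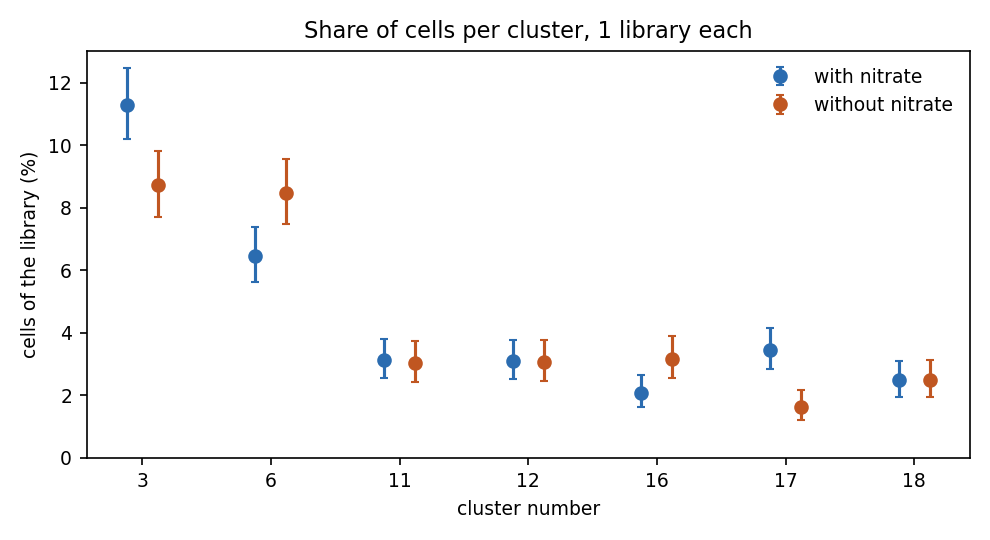
Percent of each single-cell library's cells in the 7 clusters whose leading genes did not differ between the libraries, with exact binomial 95% intervals. Cluster 17 went from 3.46% to 1.64% without nitrate, cluster 3 from 11.3% to 8.72% and cluster 6 from 6.46% to 8.47%; the other 4 clusters had overlapping intervals.

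Within clusters, UMIs of the 4 identifiers were unevenly placed. With nitrate, Zm00001d018161 was highest in cluster 17 at 156.6 CPM (118.6 to 202.9) and next highest in cluster 13 at 111.1 (84.4 to 143.7). Without nitrate, cluster 17 held 0 UMIs of this gene against 57, at least 5.41-fold lower in CPM when 3 UMIs are taken as the floor, and cluster 13 held 1 against 58, a ratio of 0.0371 (9.24e-04 to 0.215). Cluster 15 was an exception, with 6 UMIs with nitrate and 14 without, a ratio of 1.38 (0.498 to 4.38). Zm00001d017095 was concentrated in cluster 9, at 2649 CPM with nitrate and 925.8 without, a ratio of 0.349 (0.282 to 0.429). In cluster 13 its ratio was 0.436 (0.347 to 0.544) and in cluster 10 it was 0.0654 (0.0237 to 0.145). In cluster 10, 8 of the 10 leading genes differed between the libraries, so its cells may not be comparable. Of 9 clusters with at least 20 UMIs of Zm00001d017095, 7 had an interval below 1, and cluster 19, where 6 of the 10 leading genes differed between the libraries, had one above 1, from 3 and 35 UMIs. Background RNA was not measured, but when the most that the clusters with fewest UMIs per cell allow (at most 0.0417 UMIs per cell, if alike in every cell) was taken off with nitrate, 6 of the 7 still had an interval below 1, cluster 1 being the exception.

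Zm00001d052194 was higher without nitrate in 7 of 12 clusters with at least 20 UMIs, among them cluster 15 at a ratio of 2.22 (1.95 to 2.53), cluster 1 at 1.98 (1.76 to 2.24) and cluster 5 at 1.502 (1.39 to 1.62). All 7 intervals stayed above 1 with background of at most 0.0656 UMIs per cell taken off without nitrate. The highest ratio, 17.3 (7.72 to 48.1) from 6 and 120 UMIs, was in cluster 19, whose cells may not be comparable. In cluster 17 it was lower, at 0.398 (0.226 to 0.659). Zm00001d033710 was counted mainly in cluster 5, with 78 UMIs with nitrate and 354 without, a ratio of 2.66 (2.08 to 3.44). Clusters 5 and 15 held the cells with the most UMIs, with medians of 13712 and 17589 with nitrate and 21365 and 38659 without, and doublets could not be called in these libraries. The smaller mitochondrial share without nitrate was seen in 13 of 19 clusters, counted by sign alone. It went from 1.209% to 0.872% in cluster 7, but only from 1.208% to 1.187% in cluster 9. In cluster 5, which held the most UMIs, it went from 0.174% up to 0.197%, and it was also higher without nitrate in clusters 6, 12 and 17. Named genes at least 2-fold apart within a cluster went both ways. Examples lower without nitrate were matK of the plastid in cluster 10, at a ratio of 0.448 (0.308 to 0.638), and rps12 of the mitochondrion in cluster 7, at 0.472 (0.266 to 0.806). In each of clusters 10 and 7, 8 of the 10 leading genes differed between the libraries, so their cells may not be comparable either. Examples higher without nitrate were atp9 in cluster 9, at a ratio of 2.51 (1.62 to 3.87), and rpl20 of the plastid in cluster 5, at 3.73 (1.76 to 9.11). In cluster 6, where 0 of the 10 leading genes differed, cox2 was at 2.35 (1.27 to 4.62), from 14 and 47 UMIs.

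**Figure D3:**
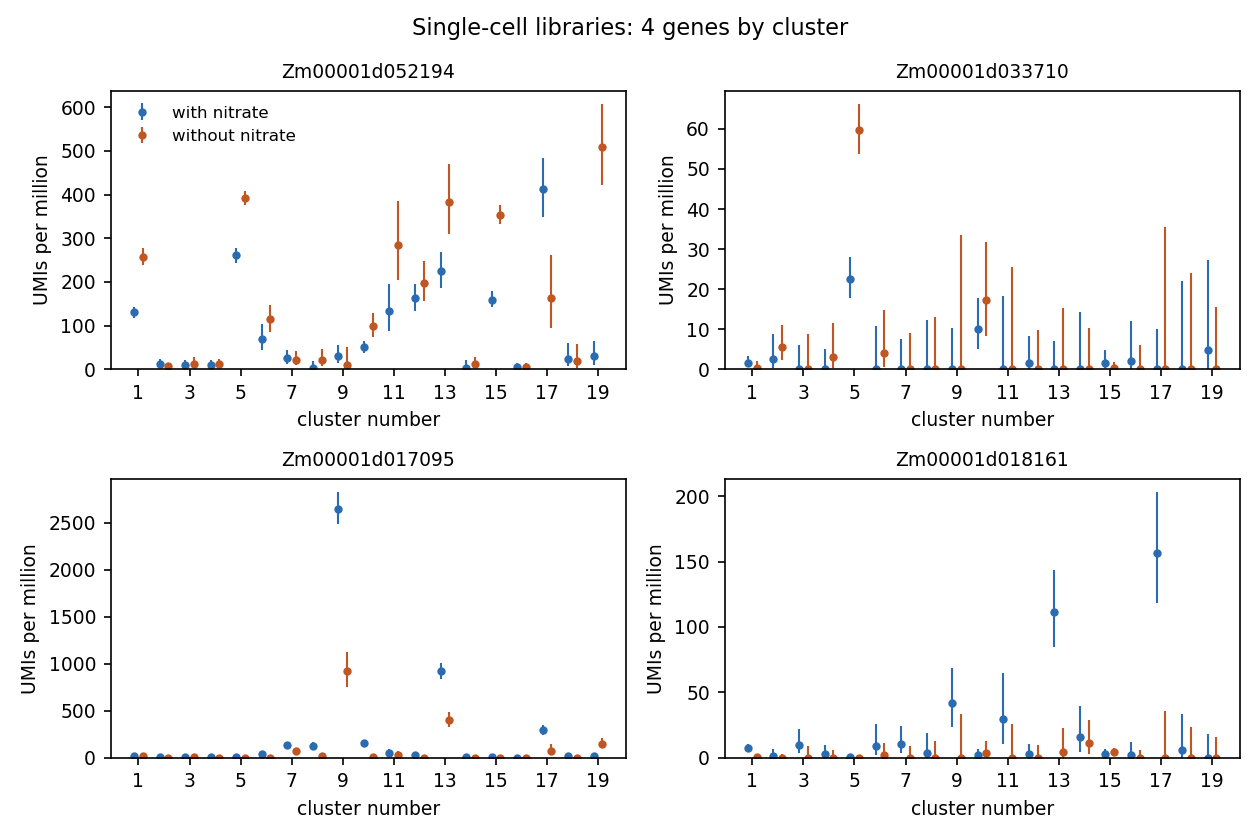
UMIs per cluster, scaled to CPM, of the 4 identifiers in the 19 compared clusters, for the library with nitrate and the library without, with exact Poisson 95% intervals. Zm00001d018161 had 156.6 CPM in cluster 17 with nitrate and 0 UMIs there without it, and Zm00001d033710 was counted mainly in cluster 5.

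The leading genes of the clusters, taken as sets of 100, were compared in the bulk libraries, a set of comparisons chosen after the fixed lists had found no members. Of these 20 sets, the mitochondrial genome with 13 genes included, limma's camera with a preset correlation of 0.01 gave 14 an adjusted p under 0.05, 6 higher and 8 lower. Among these, genes of cluster 17 had a bulk median log2 fold change of 0.60 and those of cluster 10 one of 0.52. Medians were also positive for clusters 14 (0.30), 9 (0.28), 3 (0.14) and 4 (0.11), and negative for clusters 8 (-0.42), 5 (-0.38), 18 (-0.33), 16 (-0.29), 11 (-0.29), 2 (-0.26) and 1 (-0.25). The mitochondrial genome had a median of -0.92. Of the sets that did not pass, cluster 19 was farthest from 0, at 0.22 (camera's adjusted p = 0.0634). With 1 library left out, its median ran from 0.0433 to 0.534. With a correlation estimated for each set camera gave 0 calls, at a lowest adjusted p = 0.426 with an estimated correlation, and fry also gave 0. Single libraries moved several medians by more than 1.5 times. Leaving out the second library with nitrate put cluster 9 at 0.0601, where camera's adjusted p was 0.0937, cluster 4 at 0.18, cluster 10 at 0.86, cluster 16 at -0.45 and the mitochondrial genome at -1.52. Without the first library with nitrate, cluster 9 was at 0.43, clusters 3 and 4 at 0.0767 and 0.0575, cluster 2 at -0.148, cluster 10 at 0.27, cluster 16 at -0.15 and the mitochondrial genome at -0.57. Without the first library lacking nitrate, cluster 17 was at 0.38 and cluster 11 at -0.16, and without the second, cluster 2 was at -0.151 and cluster 4 at 0.17. The call of cluster 3 was lost without the first library with nitrate or the second lacking it, that of cluster 2 without the second lacking it, and that of cluster 1 without the first of either group, where its median was -0.0563 and 0.0597; it was -0.40 without the second with nitrate.

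Bulk and single-cell differences did not go the same way across genes. Over 19304 genes with at least 20 UMIs, Spearman's rho between the bulk log2 fold change and the single-cell log2 ratio was -0.114, and 47.5% of genes had the same sign. With every cluster weighted equally these were -0.113 and 45.2%. Among the 651 genes with an absolute bulk log2 fold change of at least 1, a choice that by itself enlarges a correlation, rho was -0.339, and -0.0170 with every cluster weighted equally. Genes are not independent replicates, so these values describe the libraries. In a fit over all 6 libraries with the assay as a term, edgeR called 0 of 23626 genes, with 2130 at an unadjusted p under 0.05 and a lowest adjusted p of 0.408. A test of the interaction between assay and nitrate also called 0, with 2457 at an unadjusted p under 0.05 and a lowest adjusted p of 0.280. Its spread came from the bulk replicates alone, since each condition had 1 single-cell library. The 0 calls therefore do not show that the assays went the same way.

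**Figure D4:**
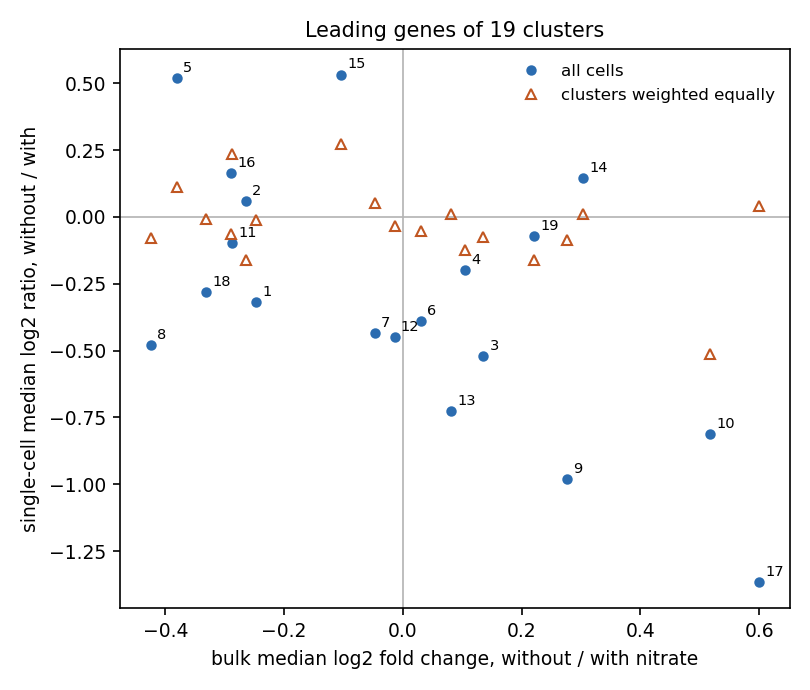
Median log2 fold change without over with nitrate of the 100 leading genes of each of 19 clusters, in bulk (horizontal) and in the single-cell libraries (vertical). Filled circles with cluster numbers sum all cells and open triangles weight the clusters equally; genes of cluster 17 were at 0.60 in bulk and -1.37 in single cells, and at 0.04 once clusters were weighted equally.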

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

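All tests of explanations in this part were chosen after the results had been seen. The bulk and the single-cell libraries moved apart for the leading genes of 8 clusters, in the sense that both bulk libraries without nitrate lay on one side of both with nitrate while the single-cell median had the opposite sign; the difference was not tested for these sets. The bulk median log2 fold changes were 0.60 for cluster 17, 0.52 for cluster 10, 0.28 for cluster 9, 0.14 for cluster 3 and 0.11 for cluster 4, with single-cell medians of -1.37, -0.81, -0.98, -0.52 and -0.20. They were -0.38 for cluster 5, -0.29 for cluster 16 and -0.26 for cluster 2, with single-cell medians of 0.52, 0.16 and 0.0586. Several of these bulk medians rest on single libraries. Without the first library with nitrate, cluster 3 was at 0.0767 (camera's adjusted p = 0.0745), cluster 4 at 0.0575, cluster 2 at -0.148, cluster 10 at 0.27, cluster 16 at -0.15 and cluster 9 at 0.43. Without the second, cluster 9 was at 0.0601 (adjusted p = 0.0937), cluster 4 at 0.18, cluster 10 at 0.86 and cluster 16 at -0.45. Without the first library lacking nitrate, cluster 17 was at 0.38, and without the second, cluster 2 was at -0.151 (adjusted p = 0.144), cluster 3 at 0.12 (adjusted p = 0.307) and cluster 4 at 0.17. The median over all genes compared was -0.13 in single cells. Of 12 sets without overlap in bulk, 4 had the same sign in both assays.

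Cells of the single-cell libraries may have been recovered in other proportions than those the bulk tissue held, which were not measured. The clusters were weighted equally to see what was left of the single-cell medians in the 8 sets. Their size, whatever the sign, was a median of 0.307 of what it had been (0.115 with signs kept). The sets were chosen in these same libraries as genes highest in each cluster, so their summed level follows the cluster's share of cells. Equal weights, or equal shares, thus take out much of the shift by construction, and tell nothing of proportions in the bulk tissue. Over all genes, Spearman's rho between bulk and single cell was -0.113 with equal weights and -0.114 without. With only the shares of cells made equal between the libraries 0.381 was left (0.362 to 1.196 when the sets were resampled), under 50% in 5 of the 8. Because of how the sets were chosen, this is no support for shares of cells as the cause. More was left for cluster 10, with -0.47 of -0.81, and cluster 4 went from -0.20 to -0.24. Clusters 2 and 16 changed sign, from 0.0586 to -0.13 and from 0.16 to -0.0609. With only the UMIs per cell of each cluster made equal 0.826 was left (0.647 to 0.968), under 50% in 0 of the 8, which argues against UMIs per cell as the main source. A swap of the nitrate labels of the 2 single-cell libraries cannot be told apart from other causes by the 308 genes strong in bulk (absolute log2 fold change of at least 1, unadjusted p under 0.01), of which 33.4% had the same sign over all cells and 48.1% with clusters weighted equally. In edgeR's fit over all 6 libraries, exchanging these labels gave 3010 genes at an unadjusted p under 0.05, against 2130 as labelled. Since the 2 assays moved apart for many genes whatever the cause, this does not decide between a swap and other causes. An effect of nitrate on the makeup of the root tip stays open and untested, as does whether plants or digestion set the shares of cells.

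The second pattern is the lower share of mitochondrial transcripts without nitrate in both assays. In single cells the ratio of their share of UMIs was 0.738, and with clusters weighted equally it was 0.921 (0.859 to 0.990 when clusters were resampled). With only the shares of cells made equal it was 0.858, with only the UMIs per cell made equal 0.781, and with both made equal 0.904. No interval was computed for these values, and the resampled one reached down to 0.859. Shares of cells thus cannot be told apart from changes within cells as the larger part of the single-cell difference. In bulk the ribosomal RNA genes dominate, and carry-over of ribosomal RNA may differ between libraries; the mitochondrial CPM outside ribosomal RNA had a ratio of 0.606, but the groups came as close as 13.4 and 12.7. Carry-over in the bulk libraries thus cannot be told apart from a lower transcript level, since few counts lie outside ribosomal RNA. A response to nitrate itself remains open and untested.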

How the results depend on the processing

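The crossed pairing, the gene sets and their settings, the smaller gene choices by unadjusted p, the comparison of 2 assays with equal weights, shares or UMIs per cell and the removal of high doublet scores were chosen after seeing the data. The count of bulk genes past the adjusted threshold stayed at 0 with RLE size factors, library size alone, limma-voom, a CPM filter and a fold threshold, but was 885 with DESeq2 and 405 without a filter, where more genes were tested; the cause was not tested. Leaving out 1 library gave 0 to 100 calls. The labels do not say that replicate numbers pair libraries, so the main fit had no block. Same-numbered libraries deviated from their group means with a correlation of -0.31 across genes. In edgeR the replicate block gave 0 calls, with 2506 genes at an unadjusted p under 0.05 against 3960, and the crossed pairing gave 1622 calls. Of the 20 gene sets, 14 passed in the main setting and with RLE, 15 with the replicate block, 14 to 17 with 1 library left out, and 0 with an estimated correlation. The median of cluster 7 genes was 0.24 without the first library with nitrate and -0.42 without the second, that of cluster 13 was 0.43 and -0.39, and that of cluster 1 was -0.25 but ran from -0.40 without the second library with nitrate to 0.0597 without the first lacking it; the cause was not tested. Over the 12 alternative fits the log2 fold change ran from -1.69 to -1.61 for Zm00001d017095, -4.67 to -3.27 for Zm00001d018161, 1.00 to 1.37 for Zm00001d052194, 1.36 to 2.08 for Zm00001d033710 and -2.03 to -1.40 for rrn26.

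In the single-cell libraries the 5th to 95th percentile range of log2 ratios was 1.24 wide, 1.68 in thinned cells, where counts are fewer, 1.28 with at least 1000 genes per cell and 1.09 with clusters weighted equally; for the last 2 the cause was not tested. The median ratio of all genes was -0.11 on total UMIs and 0.0221 with TMM. The makeup overlap of 84.4% ran from 83.5% to 85.4% under other planned settings and was 86.0% without the highest doublet scores; keeping called doublets moved nothing, since 0 were called. The within-cluster median for Zm00001d017095 of -1.19 ran from -1.48 to -0.94. The Spearman correlation across genes between bulk and single cell was -0.114, -0.339 for genes with an absolute log2 fold change of at least 1, -0.246 for genes at an unadjusted p under 0.05, -0.0170 for the former but -0.113 for all genes with clusters weighted equally, -0.0833 with only the shares of cells and -0.146 with only the UMIs per cell made equal, and -0.137 to -0.0661 with 1 bulk library left out; the cause was not tested. The gene list tests and the clustering without cell cycle genes were not run, since no list had members by name. Depth limits the within-cluster values: Zm00001d033710 reached 20 UMIs in 2 clusters and Zm00001d018161 in 4.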

Other observations

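The tests in this part were chosen after the results had been seen. Across the 19 clusters, the log2 ratio of a cluster's share of cells without over with nitrate and the bulk median log2 fold change of its leading genes had a Spearman's rho of -0.598 and a Pearson's r of -0.649, and r was -0.510 without clusters 9 and 17, farthest from the median share ratio. Over the 7 clusters that met the rule for comparing shares, rho was -0.679. Over the other 12, with leading genes 2-fold or more apart between the single-cell libraries, it was -0.510, and share ratios are less certain there for that reason. Clusters are not independent samples, since the shares of a library sum to a whole and all sets were measured in the same 4 bulk libraries, so no p-value was given and the values describe these libraries.

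The fit over all 6 libraries gave 2130 genes at an unadjusted p under 0.05 for the real grouping. Of the 10 splits of the libraries into 3 and 3, 3 gave as many, the real one included. The highest of the others gave 3010, and it kept the bulk grouping and exchanged only the single-cell libraries. The other, with 2667, put the first bulk library with nitrate and both single-cell libraries against the remaining bulk libraries. These are not random regroupings, so the splits do not measure chance for the real grouping. The 10 splits are too few for a share under 0.05.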
